A study of Homo sapiens with 4 samples.

How the data were processed

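RNA from stably transduced K562 cells, an established human line from chronic myelogenous leukaemia, was measured on Illumina HumanHT-12 beadchips. The 4 arrays fall into 2 groups of 2, taken from the sample titles: cells over-expressing the zinc finger gene ZNF16, and control transductants. The titles number the replicates 1 and 2 in each group. Nothing in the labels says that the transductants of a group were derived separately, so that the p-values measure only the spread between these samples, which may be technical.

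The deposited signal values are linear bead intensity values that were summarised with GenomeStudio 2010.2, per the submitters' processing notes. They were neither background-subtracted nor scaled between arrays, as judged from the values. Each signal has a deposited detection p-value, set against the array's negative control beads, per the file headers. The table holds 34692 entries, 1 for each gene symbol, so that the signals of a gene's probes had been combined before deposit. How they were combined, the genome build and the annotation are not given in the sources used here. Detection p-values of a single probe lie on steps of 1 in 770, and 27095 entries lay on these steps on all 4 arrays (to within 0.002 of a step). The other 7597 were taken as averages over several probes. A second deposited table, the authors' processed intensity values, holds 34685 of the entries. Each of its columns followed a straight line of the same array's signal, to within 1 intensity unit in all but 1 entry on each of 3 arrays and in every entry on ZNF16 replicate 2. The slopes were 1.05, 0.985, 0.948 and 1.02 and the intercepts −406.8, −380.8, −350.3 and −402.1 for ZNF16 replicates 1 and 2 and control replicates 1 and 2. It is therefore linear, background-subtracted and scaled by array, with medians of 45.1, 40.7, 40.5 and 43.4 in the same order. Its scale, centring and direction follow from that comparison. The lines reach a processed value of 0 close to the negative-control means inferred below, 387.8, 388.8, 369.8 and 393.1 in the same order. About that mean was thus subtracted on each array, by a method that is not stated.

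The signals were corrected with the normexp model of limma 3.58.1 in R 4.3.3. The mean and SD of the negative controls were inferred from the detection p-values of the single-probe entries. The plan named the detection p-values for this, and the limit to single-probe entries was set after their steps were seen. An offset of 16 was added, and the values were quantile normalized and taken to log2. An entry was tested if its detection p was under 0.05 on at least 2 of the 4 arrays, which left 10868. The groups were compared with limma's lmFit and eBayes, ZNF16 minus control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes at least 2-fold apart in each of the 4 ZNF16 against control pairs were counted without a test. ZNF16 and KIT were read from a fit over every entry, since they did not pass the filter. INCA1 passed it and was read from the fit over tested entries. The planned choice among a gene's probes could not be made, because the table holds 1 value for each gene, and the tests were run on those values.

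Gene lists, 40 in all with 917 different genes, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The limit to single-probe entries in the background correction was set later, as were the alternatives said to be chosen after seeing the data. Lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. The second version rests on 2 residual degrees of freedom and could hardly call any list after adjustment. A list that it did not call is therefore not shown to be unchanged. The first version gives p-values that are too small where a list's genes are correlated more strongly than 0.01. The rule names ZNF16, KIT and INCA1. It then names the 12 genes with the largest change in each direction among those past the threshold, both arrays of one group lying beyond both of the other, filled up with the genes of smallest p where fewer pass. Up to 4 members with the smallest p are named from each called list and from the haemoglobin, red cell, erythroid factor, megakaryocyte and KIT lists. Genes with no current symbol are skipped, and some members of these lists are not reported here. Of the tested entries, 8957 matched a current gene of the GRCh38.p14 annotation, 6943 by symbol, 1351 by an older symbol and 663 by gene number. The table's own names are kept in the text.

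Where a gene was detected on no array of one group, the fold change is given as a bound. The dim group's mean is then taken over, for each array, the higher of the gene's own value and the lowest normalized value among detected single-probe entries. The bound holds for this background correction only. For entries averaged over several probes it is less certain, since their own values often lie above that floor. Where they do on both arrays no bound is given, only the fitted value.

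Between 9913 and 10762 entries were detected on each array. The number of arrays limits the precision. The procedure was tested on simulated data with the 10868 genes' means and the fitted variances, independent between genes, with 200 changed genes in each of 20 simulations. It recovered 5.6% of 2-fold, 83.1% of 4-fold and 98.0% of 8-fold changes, with 6.4 false calls on average. These shares hold only where 200 genes change, spread about evenly over these sizes. Fewer changed genes make the adjustment stricter and the recovery lower. In the data CD24, with a 7.22-fold difference, did not pass. Lists of 20 genes shifted by 0.4 on the log2 scale were tested at an unadjusted camera p under 0.05. They were found in 20 of 20 simulations with the preset correlation and in 12 of 20 with the estimated one. For the estimated one the direction was not checked. An unshifted list was called in 1. The simulations gave both groups the same spread and did not adjust over lists, so they do not give the power of the adjusted list test. The alternatives were other background corrections, scalings, detection filters, variance models and thresholds, the authors' processed values raised to a floor of 16, the replicate number as a block, and each array left out in turn.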

Results

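Gene expression was profiled in K562 cells carrying stable ZNF16 over-expression and in stable control transductants, with 2 arrays in each group. ZNF16 encodes a zinc finger protein, and the series asks how it affects gene expression in this erythroleukaemic line. Mean deposited signals were 956.1 and 991.8 on the ZNF16 arrays and 998.2 and 971.9 on the control arrays. The inferred negative controls averaged 387.8, 388.8, 369.8 and 393.1 in the same order, and 9913, 10574, 10762 and 10585 of 34692 gene entries were detected.

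The ZNF16 entry itself was not detected on any array. Its detection p-values were 0.404 and 0.343 in the ZNF16 transductants and 0.518 and 0.693 in the controls. The fitted log2 difference was 0.16 ± 0.19 (SE, 2 arrays in each group; limma adjusted p = 0.924), and it became −0.026 without control replicate 2. The value combines several probes, and whether any of them lies in the transduced sequence is not given in the sources used here, so the entry does not check the labels. KIT, the stem cell factor receptor, was likewise not detected on any array, with detection p-values between 0.135 and 0.387. The KIT entry also combines several probes, so that a single detected probe could be hidden in it. Its fitted difference was −0.37 ± 0.17 (SE; limma adjusted p = 0.792). That size depended on the processing, with −0.16 when no background was removed, −0.02 with negative-control statistics from all entries (chosen after seeing the data), −1.70 in the authors' processed values and −0.23 without control replicate 2. INCA1, which encodes an inhibitor of cyclin-dependent kinase that binds cyclin A1, was detected on 2 ZNF16 arrays and 1 control array. Its log2 fold change was 0.26 ± 0.23 (SE; limma adjusted p = 0.784), and 0.09 with no background correction and 0.12 without control replicate 2.

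**Figure D1:**
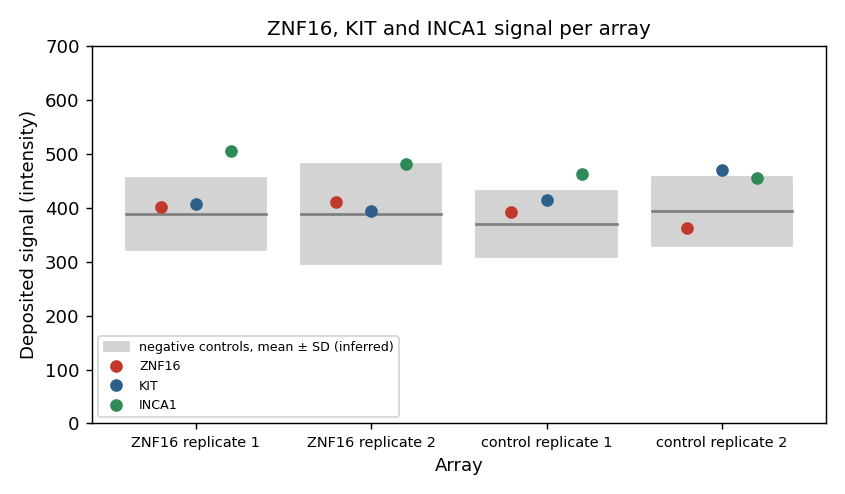
Deposited signal (intensity, vertical axis) of ZNF16, KIT and INCA1 on each of the 4 arrays, with the inferred negative controls as a line (mean) and a grey band (SD on either side). The ZNF16 points lie inside the band on all 4 arrays, at 400.8 and 410.7 in the ZNF16 transductants and 392.8 and 362.6 in the controls.

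The genes with the smallest p were DLK1, CD24 and SCIN. DLK1, a transmembrane protein related to Notch ligands, was detected on both ZNF16 arrays and on neither control array, and its signal was at least 8.66-fold higher with ZNF16 under this background correction. The bound is less certain than others, since the entry combines several probes and on 1 control array its own value was used. CD24, a glycosylphosphatidylinositol-anchored surface glycoprotein, had a log2 fold change of −2.85 ± 0.25 (SE), a 7.22-fold difference. SCIN, which encodes the actin-severing protein scinderin, had a log2 fold change of −2.32 ± 0.21 (SE), a 4.99-fold difference. Each had a limma adjusted p of 0.0545, just short of the threshold, and both arrays of one group lay beyond both of the other. No gene passed in limma's test, with 0 higher and 0 lower among 10868. At an unadjusted p under 0.05 there were 399 higher and 436 lower, 835 in all, where 543 would be expected by chance. The sizes depended on the background correction. With none, the log2 fold changes of DLK1, CD24 and SCIN were 1.67, −1.76 and −1.46, and with negative-control statistics from all entries, chosen after seeing the data, they were 0.57, −0.91 and −0.72. DLK1, CD24 and SCIN passed with a trended and robust variance model (adjusted p = 0.0382 for each), with normexp by maximum likelihood (0.0382) and with median scaling (0.0162). With 1 array left out the counts of genes past the threshold were highest without control replicate 1. The only control was then control replicate 2, which stood apart from the other arrays, as described below.

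Of the next genes higher with ZNF16, none passed the test. ISOC1, an isochorismatase domain protein, had a log2 fold change of 2.02 ± 0.22 (SE; limma adjusted p = 0.109). The nucleolar RNA polymerase I subunit CD3EAP (now POLR1G) had 1.77, the adhesion protein NINJ2 1.68, and KYNU, the kynureninase of tryptophan breakdown, 1.63. HNRNPAB, an RNA-binding protein, had 1.41 and TMEM14A 1.38. ARHGAP22 had 1.29, the phosphate transporter SLC20A2 1.28, and the nuclear kinase HIPK2 1.27. UBE2G1, a ubiquitin-conjugating enzyme, and TMEM150A were 2.297-fold and 2.295-fold higher. The adjusted p of the genes after ISOC1 lay between 0.243 and 0.254. Most of these sizes depended on the background correction. With none, CD3EAP, NINJ2 and KYNU had 0.69, 0.82 and 0.81, SLC20A2 0.50 and HIPK2 0.60, and with negative-control statistics from all entries CD3EAP, NINJ2 and KYNU had 0.14, 0.24 and 0.24.

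Of the next genes lower with ZNF16, none passed either. ENPP3, an ectoenzyme of basophils and mast cells, and SEMA4D, a semaphorin, were detected on both control arrays and on neither ZNF16 array. They were at least 3.32-fold and at least 2.05-fold lower under this background correction, each with a limma adjusted p of 0.109. Their log2 fold changes were −0.78 and −0.88 with no correction, and −0.17 and −0.14 with negative-control statistics from all entries, smaller than these bounds. The acrosin-binding protein ACRBP was at least 2.65-fold lower, alpha-fetoprotein (AFP) at least 2.49-fold and FMR1NB at least 1.83-fold, again with no detected ZNF16 array. With no correction these 3 had log2 fold changes of −0.79, −0.73 and −0.55, also smaller than the bounds. CD52, a small anchored glycoprotein of lymphocytes, had a log2 fold change of −2.07, C10ORF128 (now TMEM273) −1.83 and the receptor tyrosine phosphatase PTPRR −1.74. With no correction they had −1.61, −0.91 and −0.75. VCX2 and VCY had −1.60 and −1.78, but they belong to a family of near-identical genes that the array may not separate. Adjusted p-values after ENPP3 and SEMA4D ran from 0.123 for C10ORF128 to 0.243 for CD52 and FMR1NB.

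**Figure D2:**
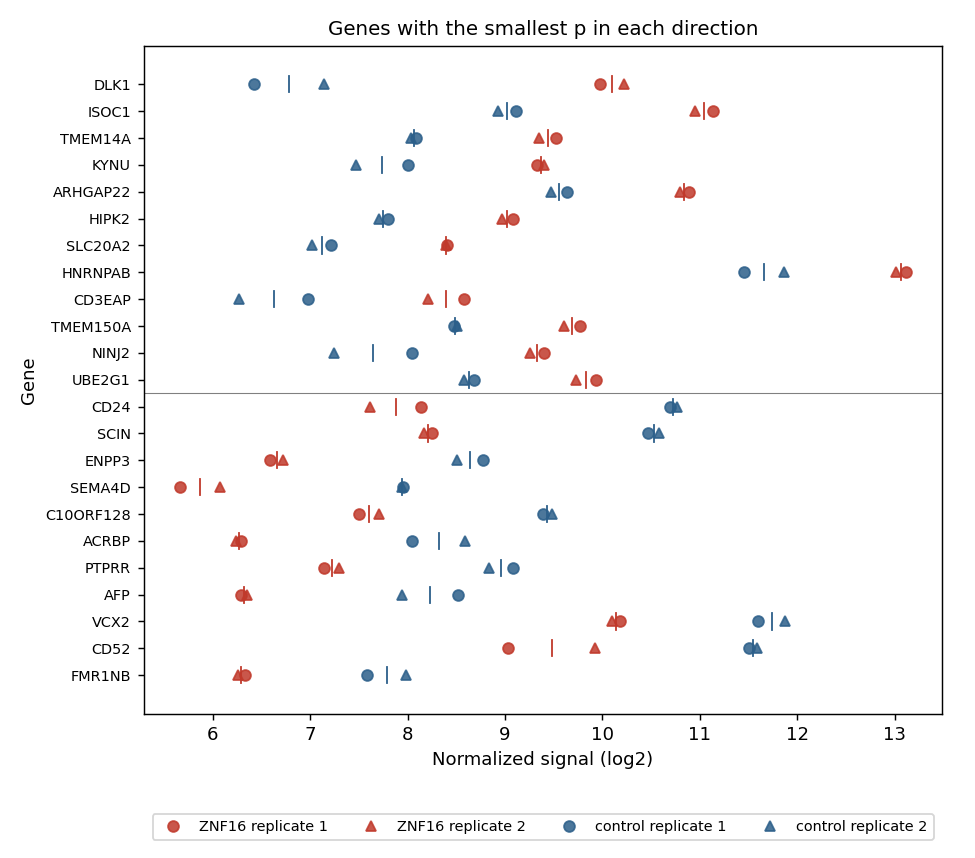
Normalized signal (log2, horizontal axis) of 23 of the 24 genes with the smallest p in each direction among those whose groups did not overlap. Each point is an array (circles replicate 1, triangles replicate 2, red ZNF16, blue control), each short line the mean of 2 arrays, and genes above the grey line were higher with ZNF16. By that choice no red point lies between the blue points of its gene. DLK1 and CD24 have the widest gaps between group means.

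Without regard to a variance model, 18 genes were at least 2-fold higher and 33 at least 2-fold lower in all 4 pairs of arrays. Median scaling in place of quantile normalization gave 3 higher and 62 lower, 4.62% higher against 35.3%. Both groups' arrays were separated in 4346 genes, 40.0% of those tested, where chance gives 33.3%. With no background correction the counts were 3 higher and 5 lower. With 1 array left out only 2 pairs remain, and the counts were 32 and 52 without ZNF16 replicate 1, 56 and 113 without ZNF16 replicate 2, 198 and 259 without control replicate 1, and 30 and 55 without control replicate 2.

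Control replicate 2 stood apart from the other arrays. The SD of log2 differences over tested genes was 0.341 between the ZNF16 arrays and 0.520 between the controls. It was 0.412 and 0.377 between control replicate 1 and the ZNF16 arrays, less than between the controls, and 0.609 and 0.524 for control replicate 2. Between the controls 641 genes were at least 2-fold apart, against 121 between the ZNF16 arrays. The first principal component, with 60.6% of the variance, placed control replicate 2 at 39.2 and the others between −23.2 and −5.29.

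No erythroid or megakaryocyte list was called. Among 10 tested haemoglobin genes, 5 were higher, 4 lower and 1 without a difference, with a median log2 fold change of 0.04 (camera adjusted p = 0.520). HBD, the delta chain of the minor adult haemoglobin, had 1.04 ± 0.21 (SE; limma adjusted p = 0.344), HBZ, the embryonic zeta chain, 0.75 and HBA2 0.30, while AHSP, the alpha-haemoglobin chaperone, had −0.87. HBE1, HBG2 and HBG1 were the brightest entries, with signals from 60392 to 68827, the highest signal of each array among them. A difference at the top of the range would not be seen in these entries. Without them, 4 of 7 haemoglobin genes were higher and 3 lower, with a median of 0.25 (adjusted p = 0.424), a setting chosen after seeing the data. Of 16 red cell membrane and blood group genes, 9 were higher and 7 lower, with a median of 0.13 (adjusted p = 0.623). Carbonic anhydrase CA2 had 0.74, tropomodulin TMOD1 0.62 and the Rh antigen gene RHD −0.72. Of 15 erythroid transcription factors and receptors, 9 were higher, with a median of 0.16 (adjusted p = 0.520). With 1 array left out this median ranged from 0.06 to 0.37. The red cell median then ranged from 0.08 to 0.18 and the haemoglobin median from 0.002 to 0.07. IKZF1 had 0.84, E2F2 0.71, STAT5B −0.65 and the erythropoietin receptor EPOR −0.62. Without control replicate 2, EPOR had −0.10 and E2F2 0.42, and without ZNF16 replicate 1 STAT5B had −0.24. Of 7 megakaryocyte and platelet genes, 5 were higher, with a median of 0.08 (adjusted p = 0.665). ANGPT1 had 0.39, the platelet tubulin TUBB1 0.34, FERMT3 −0.29 and F2RL3 0.15, and the sign of the last 3 changed when 1 array was left out. Under median scaling the median of all tested genes was −0.19 instead of 0.01, and the medians of these 4 lists were below 0. Relative to all genes they were then 0.03, 0.07, 0.04 and 0.10, against 0.03, 0.12, 0.15 and 0.06 with quantile normalization.

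Of 14 genes of KIT signalling, 4 were higher and 10 lower, with a median of −0.24 (camera adjusted p = 0.281). The tyrosine kinase FES, detected on no ZNF16 array, was at least 1.32-fold lower under this background correction (log2 fold change −0.24 with none), SOCS1 had −0.98 and the adaptor SH2B3 −0.43, none past the test. On this list control replicate 2 had a median of 0.39 above control replicate 1, and without it the list's median was −0.05, with SOCS1 at −0.30 and SH2B3 at −0.10. Without control replicate 1 the list's median was −0.43, and SOCS1 had −1.62.

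Of 37 lists tested, 1 was called. The list of signs of RNA quality and mitochondrial stress was lower with ZNF16, with 6 of 7 tested genes lower and a median of −0.33 (camera adjusted p = 0.0414; adjusted p = 0.782 with an estimated correlation). The estimated correlation was 0.80, but with 2 residual degrees of freedom that version could hardly call any list. The tested members of the called list are small non-coding RNAs. SNORD13, a small nucleolar RNA, had −1.08, the U1 RNA gene RNU1A3 (now RNU1-1) −0.78 and the 5S ribosomal RNA gene RN5S9 −0.33. RN7SK, which encodes the 7SK RNA, was detected on no ZNF16 array and had a fitted value of −0.73, which is no bound. It was −0.37 with no background correction and −0.11 with negative-control statistics from all entries. The median was 0.55 higher in control replicate 2 than in control replicate 1. The call was lost without control replicate 2 (adjusted p = 0.336), with a list median of −0.17, RNU1A3 at −0.50 and RN5S9 at −0.17. It was also lost without ZNF16 replicate 1 (0.312), with a list median of −0.18 and RN5S9 at −0.15, and just missed in the authors' processed values (0.0508). Without control replicate 1 and without ZNF16 replicate 2 the median was −0.60 and −0.52.

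**Figure D3:**
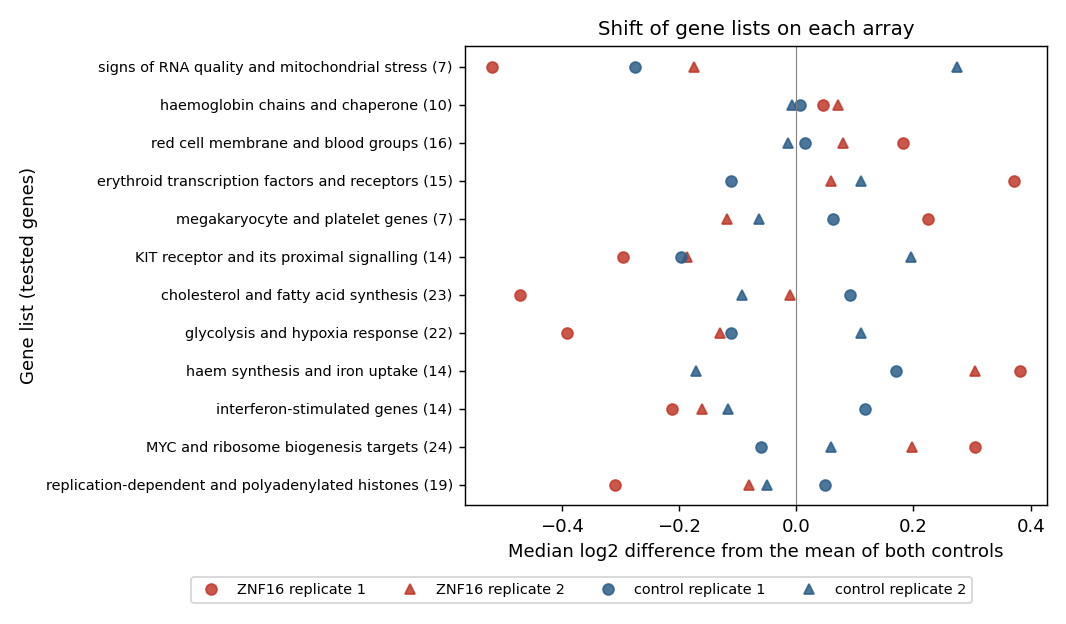
Median log2 difference of each list's tested genes (number in brackets) from the mean of both controls (horizontal axis), 1 point for each array, for the called list, the lineage and KIT lists and those with unadjusted p under 0.05. The controls mirror each other by construction, and for the RNA quality list they lie at −0.28 and 0.28, with ZNF16 replicate 2 at −0.17 between them.

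Another 6 lists had an unadjusted p under 0.05 without passing the adjustment. With an estimated correlation every list had a camera adjusted p of at least 0.782. That version could hardly call any list with 2 residual degrees of freedom, so its lack of calls decides nothing for or against these lists. The estimated correlations were 0.14 for MYC targets, 0.34 for glycolysis and 0.16 for interferon-stimulated genes. They were 0.27 for cholesterol, 0.10 for histones and 0.39 for haem synthesis. All lay above the preset 0.01, so the p-values from the preset correlation may be too small. MYC and ribosome biogenesis targets had 19 of 24 genes higher, with a median of 0.20 (camera adjusted p = 0.0568), among them MRTO4 at 0.55 and RRS1 at 0.60. The median of this list was 0.096 without control replicate 1. Interferon-stimulated genes had 10 of 14 lower, with a median of −0.17 (adjusted p = 0.0868), among them IFITM3 at −1.07 and IFITM2 at −0.80. IFI6, detected on no ZNF16 array, had a fitted value of −0.88, which is no bound, and −0.38 with no background correction. IFI6 was −0.42 without control replicate 1 and −1.34 without control replicate 2. IRF1 had 1.17, a value set by control replicate 2, where it was not detected. It was 0.04 without that array and 2.25 without control replicate 1. Without control replicate 2 both lists were called, the first higher (adjusted p = 0.00127, median 0.22) and the second lower (0.00128, median −0.40). With an estimated correlation neither list was called in that setting, where still fewer residual degrees of freedom remained. Glycolysis and hypoxia genes had 17 of 22 lower, with a median of −0.29 (adjusted p = 0.0568), cholesterol and fatty acid synthesis genes 16 of 23 lower, with −0.27 (0.164), and histones 15 of 19 lower, with −0.22 (0.168). Haem synthesis and iron uptake had 9 of 14 higher, with a median of 0.32 (0.168), including UROS at 0.99, FTH1 at 0.73 and TFRC at 0.57, and the iron importer SLC25A37 at −0.75. Without control replicate 2, UROS was 0.35, TFRC 0.37 and SLC25A37 −0.48. UROS was 1.64 without control replicate 1, and FTH1 0.43 without ZNF16 replicate 1. Control replicate 2 differed from control replicate 1 on these lists, with a median difference of −0.34 for haem synthesis, −0.23 for interferon-stimulated genes, 0.22 for glycolysis genes, −0.18 for cholesterol genes, 0.12 for MYC targets and −0.10 for histones. Without it the medians were −0.01 for glycolysis, −0.15 for cholesterol, −0.13 for histones and 0.09 for haem synthesis. Without ZNF16 replicate 2 glycolysis (adjusted p = 0.000166, median −0.39) and cholesterol genes (0.000302, −0.47) were called lower, and without ZNF16 replicate 1 their medians were −0.13 and −0.01. Glycolysis genes were also called with the replicate number as a block (0.0168), and histones with no filter on dim entries (0.0343). The haem synthesis median was 0.57 without control replicate 1. The histone median was −0.08 without ZNF16 replicate 1 and −0.32 without ZNF16 replicate 2.

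The remaining tested lists had adjusted p-values from 0.281 for HLA genes to 0.986 for sensors of viral transduction. Among lists of growth and death, median log2 fold changes were 0.15 for S phase, 0.04 for G2 and M phase, 0.18 for G1 cyclins and CDK inhibitors, −0.03 for the BCL2 family, −0.08 for the JNK pathway and −0.17 for p53 targets. Among signalling lists they were −0.07 for MAPK output, 0.18 for immediate early genes, −0.004 for BCR-ABL1 and STAT5 output, 0.05 for TGF-beta targets and 0.09 for NF-kB targets. Among stress and metabolic lists they were 0.12 for heat shock, 0.10 for the unfolded protein response, −0.09 for the ATF4 response, −0.12 for NRF2 targets, −0.11 for oxidative phosphorylation and 0.002 for cytosolic ribosomal proteins. They were −0.20 for HLA genes, 0.01 for the viral sensors, −0.16 for adhesion genes, −0.04 for progenitor markers, −0.12 for monocyte and granulocyte markers, −0.27 for markers of fibroblast and epithelial cultures, −0.02 for K562 cancer-testis antigens and −0.07 for the neighbours of ZNF16. In 14 of these 25 lists the sign of the median changed when 1 array was left out. Mean and median, or median and test, differed in sign for 4 lists, those of TGF-beta targets, the ATF4 response, BCR-ABL1 output and the viral sensors. Over all 40 lists, 0 genes passed when adjusted over all genes, and 5 higher and 13 lower passed when adjusted over the list alone.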

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

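The use of negative-control statistics from all entries, and the haemoglobin list without its brightest entries, were chosen after seeing the data, and the other alternatives were planned. The main fit's limit to single-probe entries for these statistics was also set after seeing the data, so neither version was fixed beforehand. The counts of 0 higher and 0 lower genes became 2 and 2 with normexp by maximum likelihood, 1 and 6 with median scaling, and 1 and 2 with the trended and robust variance model. Leaving out 1 array gave 0 to 43 higher and 0 to 48 lower, the highest without control replicate 1. The single array left in a group is then assumed to vary like the other group. The other settings without a block, the stricter thresholds included, gave 0 and 0. The 18 higher and 33 lower 2-fold genes became 3 and 5 with no background correction, 4 and 14 by maximum likelihood, 3 and 62 with median scaling, 11 and 9 with the strict detection filter, 60 and 100 in the authors' processed values, and 5 and 8 with negative-control statistics from all entries. They ranged from 30 to 198 and from 52 to 259 with 1 array left out, where fewer pairs must agree. In place of 0 lists higher, 1 was called with no background correction, by maximum likelihood, with no detection filter and with negative-control statistics from all entries, each time MYC and ribosome biogenesis targets. It was 0 to 1 with 1 array left out. In place of 1 list lower there were 0 with an estimated correlation, with the strict filter and in the authors' values, 2 with no filter, and 0 to 3 with 1 array left out. Apart from filters and left-out arrays, the cause was not tested.

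The replicate numbers were not taken to pair the arrays. The correlation of the replicate differences between the groups was 0.19 over only 2 pairs. With the replicate number as a block, 45 genes were higher and 77 lower, and 0 lists were higher and 2 lower. The block leaves fewer residual degrees of freedom than the 2 of the main fit, so that its calls lean further on the variance pooled over genes. The 24 genes named for their p all passed with this block. Over all 14 alternatives 57 of 326 values passed, some of them with control replicate 2 as the only control.

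With 1 array left out, the ZNF16 difference ranged from −0.026 (without control replicate 2) to 0.34, TUBB1 from −0.040 (without ZNF16 replicate 1) to 0.72, FERMT3 from −0.89 to 0.31 (without control replicate 2), and F2RL3 from −0.21 (without control replicate 1) to 0.49. F2RL3 was −0.090 with median scaling. With median scaling the list medians were −0.16 for haemoglobin, −0.12 for red cell membrane, −0.15 for erythroid factors and −0.090 for megakaryocyte genes, where the median of all genes also moved. With no filter the red cell median was −0.10, and with 1 array left out the megakaryocyte median ranged from −0.12 (without ZNF16 replicate 1) to 0.24. The 24 genes named for their p kept their direction in 144 of 144 values over the 6 alternatives that change the normalized values, with sizes down to 0.094 on the log2 scale, and 11 of these values passed the threshold. They were chosen for small p among genes whose groups did not overlap on these same arrays. Neither another normalization nor leaving out an array could therefore readily turn them, and the kept direction is no independent support. Choices among probes, and the slide as a block, were not run, since the tables used here give 1 value for each gene and no slide. Signals near the negative controls limit the dim genes, where background correction sets the fold change.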

Other observations

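The tests of exchanged labels, of 2-fold genes with no background removed and of cancer-testis genes were chosen after their results were seen. The genes in this paragraph were also chosen after their values were seen. The mast cell and basophil, T and NK cell and B cell lists were too short for the list test. Of 4 tested mast cell and basophil markers, ENPP3 is described above, PRG2, the eosinophil granule major basic protein, had a log2 fold change of −0.83 (limma adjusted p = 0.555), CLC −0.16 and GATA2 −0.05, the last with a sign that changed when 1 array was left out. CD33, a myeloid surface lectin, had a log2 fold change of −1.45 (adjusted p = 0.301), while CEBPA had 0.20. Without control replicate 1, CLC had −0.30 and CEBPA 0.05, and without control replicate 2 they had −0.009 and 0.33. The 3 tested T and NK cell genes had a median of −0.55, among them CD3D at −0.89 (adjusted p = 0.494). The 4 tested B cell genes had a median of −0.29, CD24 among them. Without control replicate 2 the T and NK cell median was −0.36 and the B cell median −0.15, and without ZNF16 replicates 1 and 2 in turn the B cell median was −0.10 and −0.51. In the glycolysis and hypoxia list, ENO2, the neuronal enolase, had −2.01, DDIT4, an inhibitor of mTOR signalling, −1.53, and BNIP3L, a mitophagy receptor, −0.99 (adjusted p = 0.381 for ENO2 and BNIP3L and 0.527 for DDIT4). DDIT4 was −0.83 without ZNF16 replicate 1 and −2.23 without ZNF16 replicate 2. Most of these sizes depended on the background correction. With none, ENO2, BNIP3L and CD33 had −1.07, −0.64 and −0.94, and PRG2 and CD3D had −0.45 and −0.49. With negative-control statistics from all entries they had −0.39, −0.29, −0.45, −0.14 and −0.16 in that order, but DDIT4 had −2.18.

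The difference of control replicate 2 from the other arrays was not removed by scaling. Under cyclic loess, which removes differences that depend on brightness, the SD of differences between the controls was 1.65 times that between the ZNF16 arrays (95% bootstrap interval over genes 1.61 to 1.68), against 1.53 with quantile normalization. Among the 3623 brightest tested genes the ratio was 2.22 (2.13 to 2.31), which argues against noise of dim signals as the cause. A difference between the cultures, the transductants or the RNA samples stays open, and no biological explanation was tested.

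The 51 genes at least 2-fold apart in all 4 pairs were more than the other groupings of the arrays gave. Of the 3 splits into 2 and 2, 1 gave as many, the real one, and the highest other gave 1 gene, but 3 splits are too few for a share under 0.05. Of the 51, 29 (56.9%, exact 95% interval 42.2 to 70.7) had a brighter group above the median of tested genes, but this decides nothing about background subtraction at dim signals. The change itself raises the brighter group, 52.7% of all tested genes meet the same condition, and the dimmer group lay above that median in only 11 of the 51. With no background removed, 8 of the 51 were still at least 2-fold apart in all 4 pairs, which argues against background subtraction as the cause in these 8. For the other 43 it stays open. An effect of ZNF16 and a difference between the transductant lines stay open.

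The ZNF16 entry was not raised in the ZNF16 arrays. Its difference was 0.84 standard errors and no array detected it, so an exchange of the group labels cannot be told apart from the stated labels by this entry. On 4 of 4 arrays its detection p lay off the steps of a single probe, so that a raised probe averaged with flat ones, or probes outside the transduced sequence, may account for it. The tables used here hold no value for each probe.

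A hypothesis raised by VCX2, VCY and FMR1NB was that cancer-testis genes as a class may be lower in the ZNF16 arrays. The class was put together by gene name, and 7 genes were left out, namely those that raised the question, close copies and some further members already seen to differ. Other clearly lower members, such as SPANXA2 at −1.36 and PAGE2B at −1.18, stayed in the class. The test is therefore not fully independent of the values that raised the question. The class was tested with limma's camera, adjusted together with the 37 tested lists. A first version held 56 genes and gave an adjusted p of 0.0237. It had taken in 4 genes that only share a name with the class. Without these, 33 of 52 genes were lower, with a median log2 fold change of −0.10 (adjusted p = 0.0212). The estimated correlation was 0.054, above the preset 0.01, so the camera adjusted p of 0.0212 may be too small. With an estimated correlation the adjusted p was 0.769, but with 2 residual degrees of freedom that version could hardly call any class. Without control replicate 2 the median was −0.036. The class holds 17 GAGE entries, near-identical genes that are not independent, and the list of K562 cancer-testis antigens fixed before the data were examined was not called (adjusted p = 0.394). The hypothesis stays open.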
